A study of Mus musculus with 12 samples.

How the data were processed

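RNA sequencing was done on 12 samples of suprarenal abdominal aorta, the part of the vessel above the kidney arteries, from male mice lacking the low density lipoprotein receptor (Ldlr). Per the labels' protocols, mice aged 8 weeks ate a western diet for 2 weeks and then carried a subcutaneous mini-pump for 2 more weeks. The pump delivered angiotensin II (AngII), a peptide that raises blood pressure and is used to bring about abdominal aortic aneurysm in such mice, or saline. RNA was extracted with a column kit, libraries were made with a NEBNext Ultra RNA kit and sequenced on a NovaSeq instrument as 151-base paired reads, with a mean of 43 M read pairs per sample, per the labels' protocols.

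The authors deposited a table of whole-number counts per gene symbol with 55309 rows, not normalized. Per the submitters' processing notes, cutadapt 2.3, STAR 2.7.8a, RSEM 1.3.3 and FastQC 0.11.8 were used with the mouse genome build GRCm38. The roles of these tools, the annotation release, the strand setting and any rounding are not given in the sources used here. If RSEM did the counting, the deposited counts would be estimates rounded to whole numbers. Reads from genes that share sequence, such as immunoglobulin segments, or from overlapping genes on opposite strands could have been divided among them in ways the counts cannot show, so single immunoglobulin genes are reported as uncertain. Each column was matched to its sample by title, and 0 columns of other samples were found. Gene symbols were matched to the GENCODE M21 annotation of GRCm38, in which 53569 of the 55309 rows and 20022 of the 20343 tested genes were found. Coordinates are from that annotation.

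Samples were placed in the 4 groups given by the labels, with 3 samples each. Saline was the control, and the mice given AngII were divided by the state of the aorta after infusion into no aneurysm (maximal diameter under 1.2 mm), dilation (1.2 mm or more without dissection) and dissection (bleeding within the wall). The outcome groups were therefore not assigned at random. The labels give 1 batch for all samples. They do not state that each sample came from a separate mouse, and p-values measure the spread between these samples. Within each group, every pair of samples differed by far more than counting noise (chi-square per degree of freedom 22.3 to 190), so no sample was counted as a repeat of another.

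Total counts ran from 15098219 to 30795416 per sample. The main test was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 with robust dispersion estimates, TMM scaling factors, the filterByExpr filter by group and 1 fit to all 12 samples with group as the only term. It tested 20343 genes. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and genes with an adjusted p under 0.05 were called. The comparisons were all 4 groups together, the mean of the 3 AngII groups against saline, and the 6 pairs of groups. Levels are TMM-scaled CPM, counts scaled to a fixed library total, given as mean ± SD with n = 3 per group, and log2 fold changes are given ± SE. When every sample of the lower group had 0 counts, the fold was set against a floor of 3 counts over the group and covers counting error only.

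Before the data were examined, 28 gene lists with 453 members were written from textbook knowledge of the aortic wall, its lesions and neighbouring tissues. Of these members, 438 were tested. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01 between genes, two-sided, and adjusted over all 168 list tests, and the test was repeated with a correlation estimated from the data. List calls below rest on the preset. In no aneurysm against saline the estimate was 0.972 for skeletal muscle, 0.844 for oxidative phosphorylation, 0.733 for collagen and -0.062 for adrenal genes. Where it is far above the preset, the camera p-values with the preset are too small. The rule for named genes was also fixed beforehand. For each pair of groups it took up to 8 higher and up to 8 lower genes with the largest fold change among called genes, with no overlap between the groups, at least 5 CPM in the higher group and no predicted symbol. It also took up to 4 members of each list with the smallest p, and Ldlr.

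The tests were tried on simulated counts drawn from the means and library sizes of these samples, with known fold changes in 200 genes. For dissection against no aneurysm, the step kept 19602 genes and called 0% of the genes changed 1.5-fold, 16.7% of those changed 2-fold, 57.1% of those changed 4-fold and 75% of those changed 8-fold. It also called 6 unchanged genes. The simulated genes were drawn independently of each other, and the samples differed only in library size and the set changes. False calls in the real samples, which hold more structure, may therefore differ.

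The alternatives fixed with the lists were DESeq2 size factors, the DESeq2 1.42.0 test, limma voom with sample quality weights, no filter beyond 1 count, a filter of 1 CPM in 3 samples, the replicate number as a block, a fit to only the 6 samples of a pair of groups, and leaving out each sample in turn. An alternative without the 3 samples of lowest total count (Saline 3, Dilation 1 and Dilation 2) and one with an adipocyte score as covariate were added after the data were seen. The adipocyte score is the mean log2 CPM of the adipocyte list in a sample, computed with a prior count of 2.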

Results

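The data describe gene expression in the suprarenal abdominal aorta of 12 male Ldlr knockout mouse samples, 3 given saline and 9 given AngII. The AngII samples fell into 3 outcome groups of 3, called no aneurysm, dilation and dissection. The study asked how the aortic transcriptome differs with these outcomes. Total counts were 15098219 in Saline 3, 17744925 in Dilation 1 and 19112977 in Dilation 2, and from 25666531 to 30795416 in the other samples. Levels below are TMM-scaled CPM (counts scaled to a fixed library total), mean ± SD with n = 3 per group, and log2 fold changes are ± SE from edgeR.

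Ldlr (chromosome 9, 21723483 to 21749919, GRCm38), the targeted gene, was counted in every sample, from 15.9 CPM in Dilation 1 to 50.4 CPM in No aneurysm 2. A wild type group was not analysed here, and a count over the whole gene cannot show whether a deleted part was absent. The 3 samples with the lowest total counts also had the lowest Ldlr levels apart from Dissection 1 (18.5 CPM), at 21.7 CPM in Saline 3, 15.9 CPM in Dilation 1 and 16.1 CPM in Dilation 2. Malat1, an RNA retained in the nucleus, was at 10594 CPM in Dilation 1 and 13758 CPM in Dilation 2, at 5188 CPM in Saline 3, and between 1879 and 5005 CPM in the other samples.

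Genes of tissues next to the aorta and of blood cells differed between samples of 1 group. The genes and Malat1 in these accounts of single samples were chosen after their values were seen. Acta1, the skeletal muscle actin, was at 3857 CPM in Saline 3 and at 587.5 CPM in Dissection 3, against 4.31 CPM in Saline 2 and 1.93 CPM in Dissection 1. Ighm, the immunoglobulin M heavy chain, was at 3075 CPM in Dissection 1, 1213 CPM in Dissection 2 and 121.7 CPM in Dissection 3. Th, the rate-limiting enzyme of catecholamine synthesis, was at 56.5 CPM in Dissection 1 and 39.2 CPM in Dissection 3, and at 1.10 CPM in Dissection 2. Hbb-bs, a beta globin, was at 6390 CPM in Saline 1 and 312.2 CPM in Saline 3. Fat genes differed between groups instead. Ucp1, the uncoupling protein of brown fat, was at 3738 CPM in Saline 1 and 229.1 CPM in Dissection 2. The adipocyte list mean of log2 CPM, less the saline mean, was 0.097, -0.194 and 0.098 in Saline 1, 2 and 3. In Dissection 1, 2 and 3 it was -1.405, -2.816 and -1.72.

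Across the 4 groups, 4159 of 20343 tested genes differed. The mean of the 3 AngII groups differed from saline in 4211 genes, 1935 higher and 2276 lower. Without Dissection 2 the first count was 2439, and without Saline 3 the second was 2630. The first was 2746 without the 3 samples of lowest total count, 6880 by DESeq2 and 8747 by limma voom. With the adipocyte score as a covariate the counts were 250 and 72, and all 72 were higher.

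**Figure D1:**
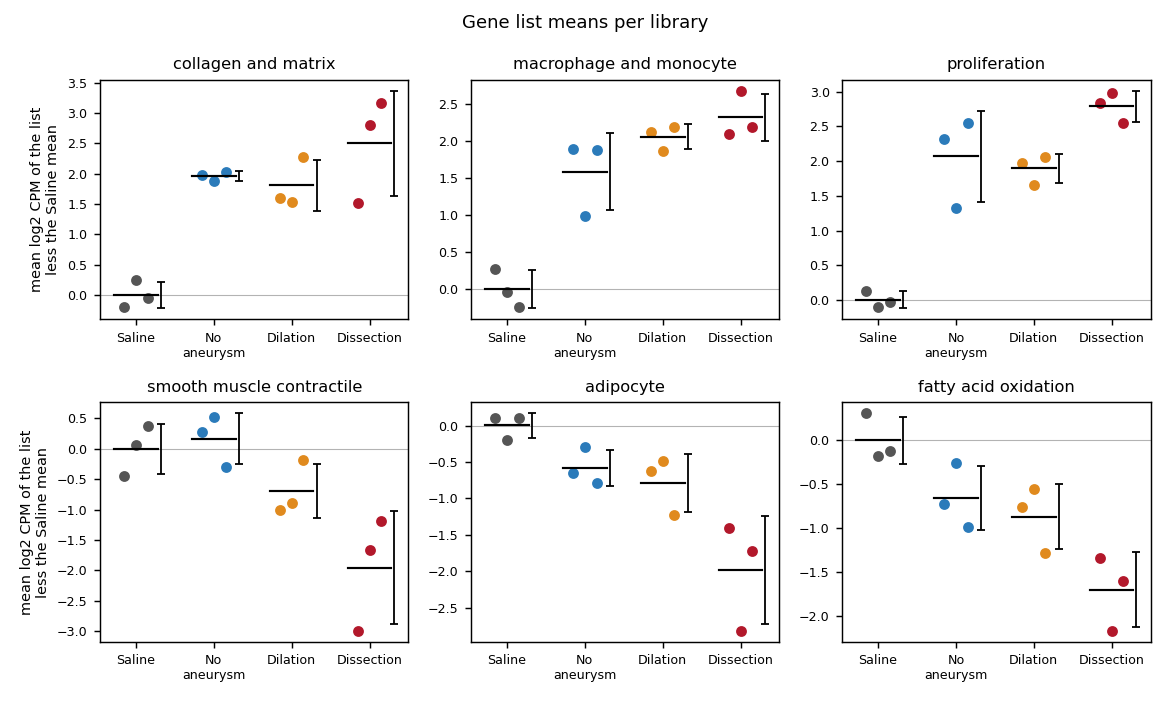
Mean log2 CPM of 6 gene lists in each sample, less the mean of the saline samples, by group. Points are samples, horizontal lines are group means and bars are SD (n = 3). The proliferation mean lay between 1.328 and 2.987 in the 9 AngII samples, and the contractile mean lay at -2.997, -1.671 and -1.194 in the dissection samples.

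Aortas given AngII that stayed under the aneurysm diameter differed from saline aortas in matrix, macrophage and cell division genes, among others. Of 24 collagen and matrix genes, 15 rose and 0 fell (23 and 0 when adjusted over the list alone). Col1a1, a chain of type I collagen (chromosome 11, 94936224 to 94953042), rose from 561 ± 109 to 3740 ± 767 CPM (log2 fold change 2.74 ± 0.34). Ccn2, a matricellular growth factor, rose from 302 ± 43.2 to 1900 ± 708 CPM, and Tnc, tenascin C, rose from 85.4 ± 8.47 to 336 ± 30.2 CPM. Camera placed this list above other genes at adjusted p = 5.33e-35, and at adjusted p = 0.261 with an estimated correlation.

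Of 22 macrophage and monocyte genes, 16 rose and 0 fell (19 and 0 when adjusted over the list alone). Trem2, a lipid-sensing receptor of macrophages (chromosome 17, 48346401 to 48354147), rose from 5.47 ± 0.525 to 43.5 ± 17.4 CPM (edgeR adjusted p = 0.0024). Cd68, a lysosomal protein of macrophages, rose from 13.7 ± 1.90 to 57.6 ± 15.5 CPM. The chemokine Cxcl16 rose from 11 ± 1.5 to 54.4 ± 14.3 CPM (log2 fold change 2.31 ± 0.19). Of 18 proliferation genes, 15 rose and 0 fell (18 and 0 when adjusted over the list alone), among them Top2a, which untangles DNA, from 3.98 ± 0.772 to 22.3 ± 8.71 CPM. The camera test gave adjusted p = 2.46e-33 for the macrophage list and for the proliferation list, and adjusted p = 0.225 for both with an estimated correlation.

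Matrix protease and elastic fibre genes rose in the same comparison. Of 23 protease and inhibitor genes 13 rose (19 when adjusted over the list alone), and Timp1, an inhibitor of metalloproteinases, rose from 8.92 ± 2.64 to 165 ± 121 CPM. Of 21 elastic fibre genes 7 rose (16 when adjusted over the list alone), among them Lox, which crosslinks elastin and collagen, from 51.9 ± 6.82 to 287 ± 48.7 CPM. Cytokine and chemokine genes rose in 7 of 21 (15 when adjusted over the list alone), with Ptgs2, an inducible cyclooxygenase, from 3.38 ± 0.398 to 21.6 ± 5.39 CPM. For these lists camera gave adjusted p = 8.85e-22 for proteases (adjusted p = 0.225 with an estimated correlation), 6.45e-16 for elastic fibre (adjusted p = 0.337) and 4.75e-15 for cytokines (adjusted p = 0.281).

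Smaller groups of called genes lay in the lists of TGF-beta signalling (4 of 16 higher), unfolded protein response (4 of 15 higher) and adventitial fibroblast (2 of 14 higher). Adjusted over the list alone, these counts were 6, 10 and 10. Serpine1, a plasminogen activator inhibitor, rose from 109 ± 18.0 to 586 ± 220 CPM, and Lum, the proteoglycan lumican, rose from 42.5 ± 5.33 to 233 ± 71.5 CPM. By camera the adjusted p was 9.42e-07, 1.24e-06 and 8.38e-07, and adjusted p = 0.348, 0.337 and 0.458 with an estimated correlation. Most of these single calls depended on which samples were included. The 4 called unfolded protein response genes, Hsp90b1, Manf, Pdia6 and Sdf2l1, lost theirs in 9, 6, 5 and 4 of the fits that left out 1 sample. Tgfb2, Inhba and Ltbp2 of the TGF-beta list and Smoc2 of the fibroblast list lost theirs in 5, 5, 8 and 5 fits. Energy and fat genes were lower as sets with 0 members called, at camera adjusted p = 6.57e-12 for oxidative phosphorylation (21 of 22 lower when adjusted over the list alone) and 0.00236 for adipocyte genes (0 of 15). With an estimated correlation these were adjusted p = 0.458 and 0.611. Mitochondrial genes held 10.1 ± 1.25 percent of counts in saline and 6.71 ± 1.02 percent in no aneurysm. Of 20 contractile smooth muscle genes, 0 were called. The largest falls among the named genes included Adra2a, an adrenergic receptor, from 12.7 ± 3.09 to 3.57 ± 0.787 CPM.

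In total 577 genes differed between no aneurysm and saline, 544 higher and 33 lower. The count was 316, 149 and 232 without Saline 1, 2 and 3, 147 without No aneurysm 1 and 140 without No aneurysm 3, 51 without the 3 samples of lowest total count, 129 with the adipocyte score as a covariate, 1859 by DESeq2 and 3055 by limma voom. DESeq2 called 1185 higher and 674 lower, limma voom 1667 and 1388, and the fit to the 6 samples alone 567 and 134. Of the 48 genes that the naming rule took here and that were called, 23 stayed called whichever sample was left out. These include the genes given with their levels above. With the adipocyte covariate 24 of the 48 stayed called, and without the 3 samples of lowest total count 10 did. In that fit Tnc, Trem2, Cxcl16 and Ptgs2 kept their calls, and the other genes given with their levels above lost theirs.

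In dilated aortas the same kinds of list stood above saline. Of 22 macrophage genes 16 rose (17 when adjusted over the list alone), with Trem2 at 108 ± 23.3 CPM (log2 fold change 4.31 ± 0.28) and Lgals3, galectin 3, from 34.2 ± 5.68 to 325 ± 29.2 CPM. Collagen and matrix genes rose in 15 of 24 (21 when adjusted over the list alone), and Col8a1, a short-chain collagen of vessels, rose from 16.5 ± 7.12 to 139 ± 17.7 CPM. Proliferation genes rose in 16 of 18 (18 when adjusted over the list alone), and Mki67 rose from 7.57 ± 0.906 to 43.6 ± 5.23 CPM. In the camera test, adjusted p = 5.75e-39, 2.86e-22 and 8.85e-22, and adjusted p = 0.225, 0.337 and 0.281 with an estimated correlation.

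Spp1, osteopontin, was among the 8 largest rises in dilation that the naming rule took, from 12.5 ± 2.35 to 471 ± 139 CPM. Mmp12, the macrophage elastase, rose from 6.98 ± 4.17 to 91.1 ± 19.2 CPM. Cytokine genes rose in 12 of 21 (16 when adjusted over the list alone), proteases in 13 of 23 (14) and elastic fibre genes in 11 of 21 (14). Type I interferon response genes rose in 8 of 16 (12 when adjusted over the list alone), and Ifit1 rose from 7.06 ± 1.99 to 32.2 ± 8.93 CPM, a call lost without Saline 2. Camera adjusted p was 1.22e-17 for cytokines, 1.83e-20 for proteases, 1.56e-11 for elastic fibre and 2.58e-09 for interferon genes. With an estimated correlation the adjusted p = 0.261, 0.225, 0.394 and 0.4 in that order.

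Several genes of energy metabolism were lower in dilation than in saline. Of 22 oxidative phosphorylation genes 7 fell (22 when adjusted over the list alone), and 6 of 18 glycolysis and hypoxia genes fell (7 lower and 1 higher when adjusted over the list alone). Vegfa, the vascular growth factor, fell from 439 ± 82.5 to 232 ± 23.5 CPM, a call lost without Saline 2. The camera test gave adjusted p = 1.17e-13 and 0.0056 for the 2 lists, and adjusted p = 0.418 and 0.348 with an estimated correlation. The adipocyte list was also lower, with 0 of 15 members called (camera adjusted p = 0.000103, and adjusted p = 0.52 with an estimated correlation), and its median log2 fold change of -0.77 was -1.32 without the 3 samples of lowest total count. Mitochondrial genes held 5.10 ± 1.36 percent of counts in dilation against 10.1 ± 1.25 percent in saline. Fatty acid oxidation genes were lower as a set, with 0 of 17 called and 16 when adjusted over the list alone (camera adjusted p = 7.12e-08, and adjusted p = 0.47 with an estimated correlation). Their median of -0.95 was -1.49 without those 3 samples. Skeletal muscle genes were lower as well, with 0 of 13 called and 13 when adjusted over the list alone (camera adjusted p = 0.00236, and adjusted p = 0.663 with an estimated correlation). The skeletal muscle score (list mean of log2 CPM less the saline mean) was 5.6 in Saline 3, against -1.663 in Saline 1 and -3.936 in Saline 2, and from -3.893 to -2.921 in dilation. Without Saline 3 this call was lost, with a median of -1.2 in place of -7.73 (camera adjusted p = 0.22), as it was without the 3 samples (-1.72, camera adjusted p = 0.164).

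Contractile genes were lower as a set in dilation than in saline, with 0 of 20 called, also when adjusted over the list alone (camera adjusted p = 0.00301, and adjusted p = 0.677 with an estimated correlation). The median of -0.72 was -0.47 without Saline 3 and -1.11 without Dilation 3, and without the 3 samples of lowest total count it was 0.06 and the call was lost, with the test itself still lower (camera adjusted p = 0.934). Adventitial fibroblast genes rose in 3 of 14 (7 when adjusted over the list alone, camera adjusted p = 2.46e-05, and adjusted p = 0.478 with an estimated correlation).

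In total 1564 genes differed between dilation and saline, 1086 higher and 478 lower. The count was 994 without Saline 1, 618 without Saline 2, 974 without No aneurysm 1, and 634, 1039 and 1032 without Dilation 1, 2 and 3. It was 88 without the 3 samples of lowest total count, 261 with the adipocyte score as a covariate, 829 in the fit to the 6 samples alone, 3018 by DESeq2 and 3568 by limma voom. The higher and lower calls were 1667 and 1351 by DESeq2, 1914 and 1654 by limma voom, and 257 and 4 with the covariate. Of the 66 genes that the naming rule took here and that were called, 11 stayed called without those 3 samples and 27 with the covariate. Trem2, Lgals3 and Mmp12 stayed called in both, Col8a1, Mki67, Spp1 and Ifit1 only with the covariate, and Vegfa in neither.

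Dissected aortas differed from saline in 5906 genes, 2877 higher and 3029 lower. Of 24 collagen and matrix genes 21 rose (21 when adjusted over the list alone), and Col1a1 reached 8800 ± 4080 CPM (log2 fold change 3.97 ± 0.34). P4ha3, a collagen prolyl hydroxylase subunit, rose from 0.774 ± 0.104 to 29.1 ± 12.8 CPM. All 18 proliferation genes rose (18 when adjusted over the list alone), and Mki67 reached 87.8 ± 21.8 CPM. Cytokine genes rose in 18 of 21 (20 when adjusted over the list alone), with Ccl2, a monocyte chemoattractant, from 1.55 ± 0.315 to 20.1 ± 9.12 CPM. For these lists camera gave adjusted p = 1.24e-17, 6.64e-22 and 2.59e-12, and adjusted p = 0.348, 0.281 and 0.337 with an estimated correlation.

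Of 22 macrophage genes 18 rose and 1 fell in dissection (19 and 1 when adjusted over the list alone), with Trem2 at 109 ± 9.91 CPM. Proteases rose in 15 of 23 (15 when adjusted over the list alone), and Mmp14, a membrane-bound metalloproteinase, rose from 38.5 ± 3.22 to 462 ± 176 CPM. Hmox1, heme oxygenase 1 (chromosome 8, 75093621 to 75100589), rose from 14.8 ± 0.884 to 671 ± 426 CPM (log2 fold change 5.50 ± 0.49, edgeR adjusted p = 0.0002). By camera the adjusted p was 2.12e-23 for macrophage genes and 2.45e-13 for proteases, and adjusted p = 0.261 and 0.281 with an estimated correlation.

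Contractile smooth muscle genes fell in 16 of 20 (16 when adjusted over the list alone). Myl9, a myosin light chain, fell from 1730 ± 510 to 273 ± 91.3 CPM, and Lmod1, leiomodin, fell from 494 ± 139 to 69.0 ± 33.3 CPM. Grip2, a scaffold protein (chromosome 6, 91761509 to 91827250), fell from 171 ± 45.0 to 11.8 ± 3.89 CPM, and Sost, sclerostin, fell from 223 ± 46.9 to 11.2 ± 9.11 CPM. All 22 oxidative phosphorylation genes fell, and 16 of 17 fatty acid oxidation genes fell while 1 rose (the same counts when adjusted over the list alone). Adipocyte genes moved with them, with 13 of 15 lower (15 when adjusted over the list alone), and Plin1, the lipid droplet protein perilipin, fell from 968 ± 205 to 268 ± 77.9 CPM. In the camera test, adjusted p = 1.89e-09, 9.11e-19, 3.6e-12 and 2.46e-10 for the 4 lists, and adjusted p = 0.458, 0.348, 0.348 and 0.348 with an estimated correlation. Mitochondrial genes held 3.18 ± 1.03 percent of counts in dissection against 10.1 ± 1.25 percent in saline.

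T cell genes rose in 2 of 15 and B and plasma cell genes in 3 of 13 (0 and 3 when adjusted over the list alone), at camera adjusted p = 0.00222 and 0.00669, and adjusted p = 0.668 and 0.677 with an estimated correlation. The T and B cell scores (list means of log2 CPM less the saline mean) were 2.097 and 2.262 in Saline 1, against -0.966 and -0.762 in Saline 2 and -1.131 and -1.5 in Saline 3, and 0.874 and 0.921 in Dissection 3. Their median log2 fold changes of 2.04 and 2.26 were 4.23 and 4.73 without Saline 1. Several other lists held called genes in dissection against saline. Circadian clock genes fell in 5 of 15 (5 when adjusted over the list alone), with Hlf from 32.8 ± 6.58 to 5.62 ± 0.778 CPM. Unfolded protein response genes rose in 8 of 15 (10 when adjusted over the list alone) and interferon genes in 9 of 16 (13). Elastic fibre genes rose in 14 of 21 (16 higher and 2 lower when adjusted over the list alone). Camera adjusted p was 0.0109, 0.00243, 0.000344 and 4.04e-06, and adjusted p = 0.472, 0.47, 0.576 and 0.525 with an estimated correlation. Without Dissection 3 the median of the elastic fibre list went from 1.3 to 0.81. Of 14 endothelial genes 4 fell (4 lower and 1 higher when adjusted over the list alone), among them Vwf, von Willebrand factor, from 220 ± 38.1 to 107 ± 25.9 CPM. The endothelial list as a set was not called here (camera adjusted p = 0.219). S100b, from 44.6 ± 4.43 to 16.8 ± 6.53 CPM, was the 1 called gene of 10 in the nerve and Schwann cell list, and camera did not call that list in any comparison.

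The 8 largest rises taken by the naming rule included Dbh, Th and Pirt. Dbh, which makes noradrenaline, rose from 0.218 ± 0.224 to 64.4 ± 53.7 CPM, and Pirt, with 0 counts in all saline samples, was at least 238-fold higher. Ighm rose from 92.9 ± 64.0 to 1470 ± 1490 CPM. As given above, the levels of Th and Ighm differed widely between the 3 dissection samples. The count of 5906 was 3855 without Dissection 2 and 20, all higher, with the adipocyte score as a covariate. Of the 98 called genes that the naming rule took here, 3 stayed called with the covariate, Trem2, Cxcl16 and Nefl, a neurofilament.

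**Figure D2:**
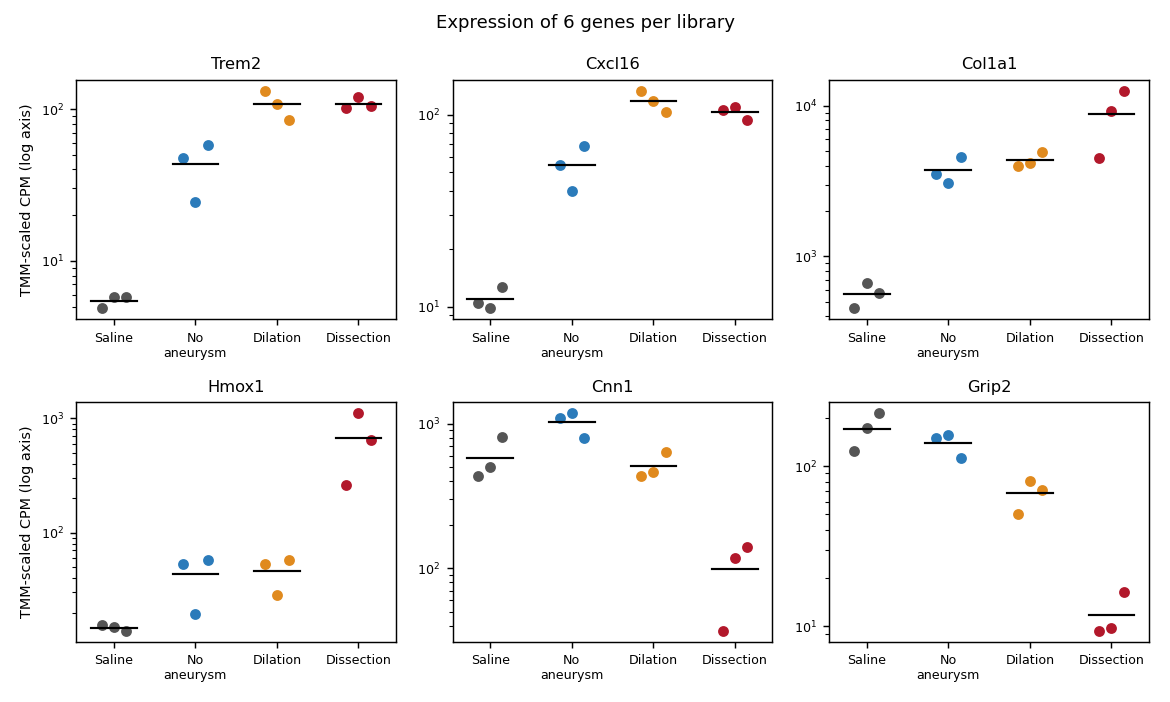
TMM-scaled CPM of 6 genes in each sample on a log axis, by group. Points are samples and lines are group means (n = 3). Trem2, Cxcl16, Col1a1 and Hmox1 were higher in dissection than in saline, and Cnn1 and Grip2 were lower.

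Between dilation and no aneurysm, edgeR called 0 genes, with 2086 at an unadjusted p under 0.05. DESeq2 called 36 and limma voom 3254. The limma voom quality weight was 0.26 for Dilation 3, against 1.65 and 1.05 for Dilation 1 and 2. In the dilation group its count therefore rests mainly on Dilation 1 and 2. Without Dilation 3, edgeR again called 0 genes, with 5413 at an unadjusted p under 0.05. Trem2 was at 108 ± 23.3 CPM in dilation and 43.5 ± 17.4 CPM in no aneurysm (log2 fold change 1.31 ± 0.27, edgeR adjusted p = 0.481). Cnn1, calponin 1, was at 511 ± 108 against 1020 ± 202 CPM, and Ifit1 was at 32.2 ± 8.93 against 11.7 ± 6.08 CPM. As a set, contractile genes were lower in dilation (camera adjusted p = 3.95e-08) and macrophage genes were higher (camera adjusted p = 7.24e-06). Interferon genes were higher too (camera adjusted p = 1.14e-06). With an estimated correlation these were adjusted p = 0.475, 0.503 and 0.47. Adjusted over the list alone, 0 contractile genes were called, 10 macrophage genes were higher and 2 lower, and 3 interferon genes were higher. The contractile score was -1.01 and -0.884 in Dilation 1 and 2, the samples of low total count and high Malat1, and -0.178 in Dilation 3, against 0.272, 0.525 and -0.292 in no aneurysm. Its median log2 fold change of -0.87 was -0.37 without Saline 3, Dilation 1 and Dilation 2 (camera adjusted p = 0.0215). The macrophage median went from 0.64 to 0.29 without No aneurysm 2, and the interferon median from 0.69 to 1.12 without No aneurysm 1.

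Lists of other cell types moved in this comparison too, with 0 members called in each. Endothelial genes were lower (median log2 fold change -0.36, 1 of 14 lower when adjusted over the list alone, camera adjusted p = 0.000145, and adjusted p = 0.4 with an estimated correlation). T cell genes (median 1.58) and B and plasma cell genes (2.73) were higher, with 0 of 15 and 0 of 13 when adjusted over the list alone (camera adjusted p = 3.77e-05 and 0.000978, and adjusted p = 0.571 and 0.638 with an estimated correlation). Their scores were 2.142 and 2.555 in Dilation 3, against 0.661 and 0.163 in Dilation 1 and 0.069 and -1.77 in Dilation 2. Without Dilation 3 both calls were lost, at medians of 0.67 and 0.62 (camera adjusted p = 0.163 and 0.649), and without Saline 3, Dilation 1 and Dilation 2 the T cell median was 2.53. Skeletal muscle genes were lower (median -1.52, 0 of 13 when adjusted over the list alone, camera adjusted p = 0.0223, and adjusted p = 0.705 with an estimated correlation). That call was lost without No aneurysm 1 (camera adjusted p = 0.085) or Dilation 3 (0.235).

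Dissected aortas differed from AngII aortas without aneurysm in smooth muscle genes, among others. Of 20 contractile genes 14 fell and 0 rose (17 when adjusted over the list alone). Cnn1 (chromosome 9, 22099216 to 22109630) fell from 1020 ± 202 to 98.4 ± 54.7 CPM (log2 fold change -3.37 ± 0.41, edgeR adjusted p = 0.003). Myl9 (chromosome 2, 156775420 to 156781658) fell from 1660 ± 294 to 273 ± 91.3 CPM. The camera test gave adjusted p = 1.19e-20, and adjusted p = 0.284 with an estimated correlation. Among the largest falls, Hhip, a hedgehog-binding protein, went from 10.3 ± 1.39 to 0.396 ± 0.079 CPM, and Ptprz1, a receptor phosphatase, from 102 ± 37.4 to 6.34 ± 2.62 CPM. Vwf fell from 299 ± 44.2 to 107 ± 25.9 CPM, and Smad6, an inhibitor of BMP signalling, fell from 43.8 ± 1.53 to 15.7 ± 3.72 CPM.

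Genes of several lists also rose in dissection against no aneurysm. Hmox1 rose from 43.2 ± 20.6 to 671 ± 426 CPM (log2 fold change 3.96 ± 0.49), Adam8, a protease of leukocytes, from 26.7 ± 9.71 to 142 ± 52.8 CPM, and Mmp14 from 125 ± 6.02 to 462 ± 176 CPM. Of 23 protease genes 7 rose and 2 fell (8 and 3 when adjusted over the list alone), and of 24 collagen genes 6 rose and 1 fell (10 and 2). Of 22 macrophage genes 5 rose and 1 fell (13 and 1 when adjusted over the list alone). For these lists camera gave adjusted p = 0.00722, 0.0219 and 3.7e-06, and adjusted p = 0.608, 0.739 and 0.484 with an estimated correlation. The protease call was lost without Dissection 2 (camera adjusted p = 0.0742), and its median log2 fold change of 0.27 was 0.13 there, 0.70 without No aneurysm 1, 0.50 without No aneurysm 3 and 0.49 without Dissection 1. The collagen call was lost without Dissection 2 (0.107) or Dissection 3 (0.566) and without the 3 samples of lowest total count (0.0633). Its median of 0.48 was 0.35 without Dissection 2, 0.14 without Dissection 3 and 0.83 without Dissection 1. T cell genes rose in 3 of 15 and B and plasma cell genes in 4 of 13 (15 and 13 when adjusted over the list alone), with Cd3g from 1.44 ± 0.857 to 14 ± 9.6 CPM. By camera the adjusted p was 1.63e-08 and 3.66e-08, and adjusted p = 0.47 for both with an estimated correlation. The 8 largest rises taken by the naming rule were immunoglobulin genes, which share sequence and are uncertain. Igkv4-57-1 had 0 counts without aneurysm and was at least 217-fold higher.

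Several fat and energy genes were lower in dissection than without aneurysm. Adipocyte genes fell in 6 of 15 (12 when adjusted over the list alone), with Dio2, a deiodinase of brown fat, from 129 ± 8.32 to 21.8 ± 12.8 CPM. Oxidative phosphorylation genes fell in 8 of 22 (22 when adjusted over the list alone) and fatty acid oxidation genes in 10 of 17 (16), with Acox1 from 473 ± 56.0 to 200 ± 45.8 CPM, a call lost without No aneurysm 2. In the camera test, adjusted p = 4.69e-11, 3.59e-12 and 2.36e-10, and adjusted p = 0.348, 0.458 and 0.4 with an estimated correlation. The mitochondrial share of counts was 3.18 ± 1.03 percent in dissection and 6.71 ± 1.02 percent in no aneurysm. Renin-angiotensin genes went both ways, with 2 higher and 3 lower of 12 (2 and 5 when adjusted over the list alone). Rgs4, which dampens G protein signals, fell from 68.0 ± 29.0 to 20.2 ± 7.43 CPM, a call lost without No aneurysm 1 or No aneurysm 2. Camera adjusted p was 0.0488, and adjusted p = 0.478 with an estimated correlation. This call was lost without No aneurysm 2 (camera adjusted p = 0.0548), Dissection 1 (0.0845) or Dissection 2 (0.0774), and the median of -0.60 was -0.97 without Dissection 3.

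In total 1593 genes differed between dissection and no aneurysm, 649 higher and 944 lower. The count was 352, 241 and 966 without No aneurysm 1, 2 and 3, 872 without Dissection 1, 574 without Dissection 2, 80 with the adipocyte score as a covariate, 3360 by DESeq2 and 3915 by limma voom. The higher and lower calls were 292 and 282 without Dissection 2, 88 and 264 without No aneurysm 1, 59 and 182 without No aneurysm 2, 63 and 17 with the covariate, and 864 and 814 in the fit to the 6 samples alone. With that covariate the median log2 fold change was -0.39 for the collagen list, -0.08 for proteases, 0.21 for macrophage genes and 0.08 for oxidative phosphorylation. In each of these 4 lists the direction of the test turned, and for the collagen list the turned result was itself called (camera adjusted p = 0.0319, against 0.173, 0.845 and 0.704 for the others). The macrophage test was lower while its median was above 0. Of the 79 genes that the naming rule took here and that were called, 18 stayed called whichever sample was left out. These include Hhip, Ptprz1, Cnn1, Myl9, Vwf, Smad6, Adam8, Mmp14, Hmox1 and Dio2. With the covariate 3 of the 79 stayed called, Hhip among them, and the other 9 of these 10 lost their calls. Cd3g lost its call without No aneurysm 1 or 2 or Dissection 1 or 2, and Igkv4-57-1 lost it without Saline 2, any no aneurysm sample, or Dissection 1 or 2.

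Against dilation, dissected aortas differed in 228 genes, 69 higher and 159 lower. Hmox1 rose from 46.5 ± 15.6 to 671 ± 426 CPM, and Marco, a scavenger receptor of macrophages, rose from 2.11 ± 1.63 to 131 ± 108 CPM. Contractile genes fell in 4 of 20 (8 when adjusted over the list alone), with Myl9 from 1030 ± 154 to 273 ± 91.3 CPM and Lmod1 from 306 ± 55.1 to 69.0 ± 33.3 CPM. Nrtn, the growth factor neurturin, fell from 31 ± 12.8 to 5.30 ± 1.36 CPM, and Grip2 fell from 67.7 ± 15.6 to 11.8 ± 3.89 CPM. The camera test gave adjusted p = 8.7e-11 for contractile genes, and adjusted p = 0.417 with an estimated correlation. Without Dilation 3 the median log2 fold change of this list went from -1.37 to -0.79.

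Fat, energy and immune cell lists moved beside the contractile list, with 0 members of each called. Over the list alone, 12 of 15 adipocyte genes, 21 of 22 oxidative phosphorylation genes and 15 of 17 fatty acid oxidation genes were lower, and 1 fatty acid oxidation gene was higher. Camera adjusted p was 1.42e-09, 5.82e-10 and 3.95e-08, and adjusted p = 0.348, 0.476 and 0.47 with an estimated correlation. The medians of -1.08, -0.76 and -0.91 were -0.53, -0.20 and -0.39 without the 3 samples of lowest total count, and 0.10, 0.08 and 0.04 with the adipocyte score as a covariate. Mitochondrial genes held 3.18 ± 1.03 percent of counts in dissection and 5.10 ± 1.36 percent in dilation.

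T cell and B and plasma cell genes were higher in dissection than in dilation, with medians of 1.65 and 1.94 and with 0 of 15 and 3 of 13 higher when adjusted over the list alone. By camera the adjusted p was 0.000452 and 2.88e-05, and adjusted p = 0.638 and 0.531 with an estimated correlation. Without Dilation 3 the medians were 2.59 and 4.59, and without the 3 samples of lowest total count both calls were lost, at 0.75 and 0.65 (camera adjusted p = 0.201 and 0.131). The T cell call was also lost with the adipocyte score as a covariate.

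The 228 calls changed with single samples. Without Dissection 2 there were 184, of which 136 were higher and 48 lower, and without Dissection 1 there were 36 higher and 37 lower. The count was 1 without Dilation 2, 33 without Dilation 1, 2435 without Dilation 3, 73 without Dissection 1, 103 and 374 without Saline 2 and 3, and 99, 103 and 98 without No aneurysm 1, 2 and 3. It was 0 in the fit to the 6 samples alone, 1 without the 3 samples of lowest total count, 39 with the adipocyte score as a covariate, 1765 by DESeq2 and 3532 by limma voom. With the covariate 37 were higher and 2 lower, and limma voom called 1577 higher and 1955 lower. Each of the genes named for this comparison lost its call without Dilation 2, without the 3 samples of lowest total count and with the covariate. Of the 25 called genes that the naming rule took here, 4 stayed called with the covariate and 0 without those 3 samples.

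Lists of neighbouring tissues and blood were also called in other comparisons, most of them without single genes passing. The skeletal muscle list was lower in no aneurysm than in saline (0 of 13 called, 13 when adjusted over the list alone, camera adjusted p = 0.0107, and adjusted p = 0.681 with an estimated correlation), and without Saline 3 its median log2 fold change was 0.17. That call was also lost without No aneurysm 2 (camera adjusted p = 0.0504). In dissection its score was -4.47, 1.446 and 3.052 in Dissection 1, 2 and 3, and it was higher as a set there than in dilation and than without aneurysm, with 0 of 13 called in each, also when adjusted over the list alone. The medians were 5.55 and 3.44 (camera adjusted p = 0.000287 and 0.0282, and adjusted p = 0.608 and 0.705 with an estimated correlation). The call against no aneurysm was lost without No aneurysm 3 (camera adjusted p = 0.0688), Dissection 2 (0.0805) or Dissection 3 (0.351, median 2.03).

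The red blood cell and platelet lists were lower in no aneurysm than in saline with 0 of 10 members called in each, also when adjusted over the list alone (camera adjusted p = 0.017 and 0.0147, and adjusted p = 0.66 for both with an estimated correlation). Their scores were 1.572 and 2.629 in Saline 1, against 0.081 and -0.677 in Saline 2 and -1.653 and -1.951 in Saline 3. Without Saline 1 both calls were lost, with median log2 fold changes of -0.39 and -0.64 in place of -1.68 and -3.25 (camera adjusted p = 0.384 and 0.699). The red blood cell call was also lost without No aneurysm 3 (-1.22, camera adjusted p = 0.0797), and its median was -3.04 without No aneurysm 2. Red blood cell genes were lower in dilation than in saline as well, with 0 of 10 called, also when adjusted over the list alone (camera adjusted p = 0.00261, and adjusted p = 0.571 with an estimated correlation), and the median of -2.58 was -1.4 without Saline 1. B and plasma cell genes were lower in no aneurysm than in saline, with 0 of 13 called, also when adjusted over the list alone (camera adjusted p = 0.0313, and adjusted p = 0.705 with an estimated correlation). Their median of -2.37 was 0.03 without Saline 1, where the test was still lower and the call was lost (camera adjusted p = 0.991), as it was without No aneurysm 1 (0.054), No aneurysm 2 (0.0742) or Dissection 2 (0.0501).

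Platelet genes were higher in dissection than without aneurysm and than in dilation, with 0 of 10 called in each, also when adjusted over the list alone (camera adjusted p = 0.0282 and 0.0303, and adjusted p = 0.677 for both with an estimated correlation). Without Dissection 1 the medians of 2.82 and 2.74 were -0.20 and 0.59 and both calls were lost, with both tests still higher (camera adjusted p = 0.469 and 0.554). The first was also lost without No aneurysm 1 (0.056) and the second without Dilation 3 (0.246), and without the 3 samples of lowest total count the second median was 4.36. Neutrophil genes were higher as a set in dissection than without aneurysm, with 0 of 9 members called and 4 when adjusted over the list alone (camera adjusted p = 0.0056, and adjusted p = 0.571 with an estimated correlation). The neutrophil score was 2.365 and 1.742 in Dissection 1 and 2 and -0.013 in Dissection 3, against 0.001, -0.923 and 0 in no aneurysm, and the median log2 fold change of 2.26 was 1.02 without Dissection 1. Of 7 adrenal genes 3 were higher in dissection than without aneurysm, Th, Dbh and Chga, and 3 when adjusted over the list alone (camera adjusted p = 0.0343, and adjusted p = 0.348 with an estimated correlation). The list call was lost without Saline 3 (camera adjusted p = 0.0508) or Dissection 3 (0.0702) and without the 3 samples of lowest total count (0.0567), and its median log2 fold change of 1.53 was 0.42 without Dissection 2 and 3.41 without those 3. Each of the 3 lost its call without No aneurysm 2, No aneurysm 3 or Dissection 1. Th also lost it without Saline 2 or Dissection 3, Dbh without No aneurysm 1, and Chga without Dilation 1 or Dissection 2. Against dilation 0 of the 7 were called, and 4 were higher when adjusted over the list alone (camera adjusted p = 0.0271, and adjusted p = 0.337 with an estimated correlation). That call was lost without Dilation 3 (camera adjusted p = 0.124) and without the 3 samples of lowest total count (0.0825), and the median of 3.34 was 1.58 without Dissection 2.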

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

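The dilution, fat and adrenal tests below were chosen only after the result was seen, as were the contrast on Camkk1 and the accounts of single samples. Camkk1, a calcium/calmodulin-dependent kinase kinase, drew attention because its log2 fold change against saline was 1.08 in no aneurysm and -1.10 in dissection, and the difference itself was -2.18 (edgeR adjusted p = 0.00237). The first of these calls was lost without Saline 1, 2 or 3, No aneurysm 1 or 3, Dilation 1 or 2, or Dissection 1, and no explanation was tested.

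Contractile smooth muscle genes were lower in dissection than in no aneurysm by 2.12 ± 0.49 as a list mean on the log2 scale. Dilution by incoming cells would lower endothelial and fibroblast genes alike if those cells did not multiply. The contractile mean changed by -1.86 ± 0.39 more than the mean of those 2 lists. Against no aneurysm, 0 of 14 fibroblast genes were higher and 2 lower in dissection, and their list mean changed by -0.19 ± 0.29. Against saline, 7 of 14 were higher and 2 lower, so these cells may not be a fixed reference. A dilution hidden by their growth cannot be excluded by this test. Loss of smooth muscle cells alone would lower other genes of these cells as much, and the mean of 8 such genes lay 1.16 ± 0.30 above the contractile mean. Those 8 genes, which pericytes also express, ran from 0.17 to -2.38 and their mean itself fell by 0.96 ± 0.39, so a partial loss of cells stays open beside a lower expression of contractile genes in the remaining ones. That lower expression may be a part is a hypothesis found and tested on the same samples.

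Genes of the respiratory chain and fatty acid oxidation were lower in dissection than in no aneurysm, with a change of -0.96 ± 0.28 in the mean of the 2 lists on the log2 scale. A candidate explanation is less fat tissue, such as brown fat, in the dissected piece. The adipocyte list holds brown fat genes such as Ucp1 and Dio2 beside general ones such as Plin1, so brown fat itself was not tested. It also holds Cox8b, a gene of the respiratory chain, so part of the correlation below may be built in. Within groups the adipocyte mean and this mean were correlated over 12 samples (Pearson r = 0.94, exact permutation p = 0.00154 over 1296 within-group orders, Spearman rho = 0.95, exact permutation p = 0.00154, both adjusted p = 0.00205 over 4 correlations), and r was 0.92 without the 2 farthest samples. With the adipocyte mean as a covariate the change was 0.03 ± 0.17. That mean also differs between the groups, so the covariate takes up part of the group difference. Fewer fat cells and lower expression within fat cells were not separated by this test, and the outcome itself and the lower share of mitochondrial counts in dissection, not tested as an explanation, stay open.

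Th and Dbh were higher in dissection, with Th at 56.5, 1.10 and 39.2 CPM in the 3 samples. Sympathetic nerve tissue in the piece is a candidate source, since the mean of 14 sympathetic neuron genes followed Th over 12 samples (Spearman rho = 0.79, permutation p = 0.00325, Pearson r = 0.96, permutation p = 4e-05, adjusted p = 0.00325 and 0.00016 over 4 correlations, and r = 0.72 without the 2 farthest samples). Here the samples were permuted across the groups, so the p-values also count the difference between groups that raised the question. In Dissection 1 and 3 the highest of the cortex genes Cyp11b1, Cyp21a1 and Hsd3b1 and the medulla gene Pnmt was 0.247 CPM, against a limit of 1 CPM. Pnmt was at 0.0644 and 0.247 CPM there and at 0.965 to 3.43 CPM in saline, where Th was at 0.298 CPM or less. Pnmt thus did not rise with Th, but 1 gene that did not follow Th in saline either cannot exclude adrenal medulla. The nerve test did not set nerve against adrenal medulla, so it cannot tell these sources apart. The 3 cortex genes had failed the low count filter before this check was chosen, so low levels were likely from the start. Star, Cyp11a1 and Mc2r, cortex genes of the adrenal list that passed the filter, were not used, so adrenal cortex stays open. In Dissection 2, where Th was at 1.10 CPM, Hsd3b1 was at 1.82 CPM, against 0.103 CPM or less in all other samples. Pnmt, Cyp11b1 and Cyp21a1 were at 0.0865 CPM or less there, so these genes cannot tell a trace of adrenal tissue from none. The median of the adrenal list in dissection against dilation went from 3.34 to 1.58 without Dissection 2, and such a trace stays open. Whether nerve tissue came with the lesion or with the piece taken was not tested.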

How the results depend on the processing

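The alternatives without Saline 3, Dilation 1 and Dilation 2 and with the adipocyte score as covariate were chosen after seeing the data. Over the samples left out in turn, the counts of called genes ran from 2439 to 6188 for the 4 groups, 2630 to 4217 for AngII against saline, 140 to 699 for no aneurysm against saline, 618 to 1581 for dilation against saline, 3855 to 6707 for dissection against saline, 241 to 1951 for dissection against no aneurysm and 1 to 2435 for dissection against dilation. In the order 4 groups, no aneurysm, dilation against saline, and dissection against dilation, the counts without those 3 samples were 2746, 51, 88 and 1. With the adipocyte covariate the counts were 250 for the 4 groups and 72 for AngII, 129, 261 and 20 for no aneurysm, dilation and dissection against saline, and 80 and 39 for dissection against no aneurysm and dilation. DESeq2 called 6880 genes for the 4 groups, 1859 and 3018 for no aneurysm and dilation against saline, 36 for dilation against no aneurysm, and 3360 and 1765 for dissection against no aneurysm and dilation. For the same results limma voom called 8747, 3055, 3568, 3254, 3915 and 3532. Its quality weights ran from 0.26 for Dilation 3 to 4.35 for No aneurysm 1, so the samples counted unequally. Fits to 6 samples called 829 genes for dilation against saline and 0 for dissection against dilation. With the replicate number as a block the counts were 352 for no aneurysm against saline, 892 and 127 for dissection against no aneurysm and dilation, and 3100 for the 4 groups. Samples with the same number had a median correlation of -0.029 over 18 pairs (-0.572 to 0.224, 4 over 0.1). Those with different numbers had 0.0205 over 36 pairs (-0.44 to 0.527, 12 over 0.1). The numbers thus gave no sign of pairing, though this comparison cannot exclude a pairing of some samples. Camera called 95 of 168 list results, and 0 with an estimated correlation. The median log2 fold change of the skeletal muscle list in no aneurysm against saline ran from -6.47 to 0.17 over the samples left out in turn, turning to 0.17 without Saline 3 and also without the 3 samples. With the adipocyte covariate the medians were -0.39 for collagen, -0.08 for proteases, 0.21 for macrophage and 0.08 for oxidative phosphorylation genes in dissection against no aneurysm, and 0.01 for collagen, 0.10 for adipocyte, 0.08 for oxidative phosphorylation and 0.04 for fatty acid oxidation genes in dissection against dilation, and in each of these 8 results the direction of the test turned, which was called only for collagen in dissection against no aneurysm (camera adjusted p = 0.0319, against 0.173 to 0.987 for the others). The adipocyte score differs between the groups, so the covariate takes up part of each group difference, and the cause was not tested for any result that moved or turned. Other counts stayed within 1.5 times of the main value. The depth, 15098219 to 30795416 counts, limits genes of few counts.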

Other observations

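In this part the fits without the 3 samples of lowest total count were chosen after the result was seen, and the other tests, on gene lists and on splits of the samples, were not. Bone and cartilage genes were higher as a set in dilation than in saline, with 4 of 13 higher and 1 lower (the same when adjusted over the list alone, camera adjusted p = 0.0343, and adjusted p = 0.557 with an estimated correlation), a call lost without Dilation 2 (camera adjusted p = 0.141) and without the 3 samples of lowest total count (0.102). They were also higher as a set in no aneurysm than in saline, with 0 of 13 called and 2 higher when adjusted over the list alone. There the median log2 fold change was 0.85 (camera adjusted p = 0.0111, and adjusted p = 0.478 with an estimated correlation). Immediate early genes, which respond quickly to stimulation, were lower as a set in dilation than without aneurysm, with 0 of 15 called and 1 lower when adjusted over the list alone (camera adjusted p = 0.00273, and adjusted p = 0.638 with an estimated correlation). Their median log2 fold change of -0.63 was -1.02 without No aneurysm 1 and -0.35 without No aneurysm 2, and the call was lost without the 3 samples of lowest total count (-0.10, camera adjusted p = 0.457). Endothelial genes were lower as a set in dissection than without aneurysm, with 2 of 14 lower and 4 when adjusted over the list alone (camera adjusted p = 0.0131, and adjusted p = 0.531 with an estimated correlation), and the median of -0.23 was -0.15 without Dissection 2. The same list was lower in dilation than without aneurysm, with 0 of 14 called and 1 when adjusted over the list alone (median -0.36, camera adjusted p = 0.000145, and adjusted p = 0.4 with an estimated correlation). Between dissection and dilation camera did not call it (adjusted p = 0.985).

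Other splits of the samples were tested for each count. For the 4 groups, 1 of 100 splits, the real one, gave 4159 genes and the highest other gave 1110. For AngII against saline 1 of 100 gave 4211 and the highest other 502. Only 100 splits were drawn for each, so chance is unlikely for both counts but is not excluded. For pairs of groups only 10 splits exist and the share cannot go under 0.1. There the real and highest other counts were 577 and 1 for no aneurysm against saline (1 split as large), 5906 and 0 for dissection against saline (1 split), 1593 and 0 for dissection against no aneurysm (1 split), and 0 and 1 for dilation against no aneurysm (10 splits). For dilation against saline they were 1564 and 1954 (2 splits), the larger from placing Saline 3 with Dilation 1 and 2 and Dilation 3 with Saline 1 and 2. For dissection against dilation they were 228 and 1077 (2 splits), the larger from placing Dissection 1 with Dilation 1 and 2 and Dilation 3 with Dissection 2 and 3, which points to a structure of the samples beside the groups.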
